A study of Mus musculus with 2 samples.

How the data were processed

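Chromatin accessibility was measured by DNase-seq, in which DNase I cuts DNA that is not protected by nucleosomes and the cut sites are sequenced, in nuclei from the gastrocnemius, the main calf muscle. Both libraries came from males of the hybrid strain B6CASTF1/J, the offspring of C57BL/6J and CAST/EiJ mice, at an age of 4 days, and each label speaks of 3 males. Per the labels, the libraries are biological replicates 1 and 2 of 1 group, from separate tissue samples with the same donor entry. With 1 group there was no contrast to test, so the values are levels, with the spread between the 2 libraries, and comparisons between groups of genes, sequence motifs and regions within them. Genes and peaks are not replicates, so every p-value describes these libraries and not other animals.

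4 kinds of interval list were used for each library, all on mouse build mm10 per the file listings, and all called on 1 library by itself. The peak lists carry the authors' cut density (signal) at each peak. In each library 100% of the densities under 1 were whole multiples of 1 step, with a tolerance of 0.1 step. The densities were therefore read as counts multiplied by 1 constant per library. That this constant scales them to the depth of the library is an assumption, which the values do not show. The deposited false discovery rate (FDR, a q-value) lists give the stretches of bases with an FDR below 0.05, and the highest value found in them was 0.05 in both libraries. Each library had a longer and a shorter peak list. All peaks of the longer lists touched bases with an FDR below 0.05 and all peaks of the shorter lists touched stretches that reached 0.001, so they were read as lists at these thresholds, which no label states. The longer lists were used throughout, and the shorter ones as an alternative. Footprints, short stretches within accessible DNA that are protected from cutting, carry the constant 0.01 in every entry of the deposited lists. Its meaning is not given in the sources used here, and a constant gives no strength, so footprints could not be ranked. The aligner, the peak caller and their versions are not given in the sources used here. No list was one of broad accessible regions, so the stretches with an FDR below 0.05 stood in for it.

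The depth of the libraries can be read only as a ratio. The density steps were 0.00675 in replicate 1 and 0.00333 in replicate 2, which makes replicate 2 2.03 times as deep if 1 step is 1 cut scaled to depth. Depth in reads is not known from the files, so no counting interval is given for a density. A peak's density is the authors' own value and was used only to describe, rank and filter peaks within their own list, apart from the ratio between the libraries at paired peaks, which was described, set against GC content and compared between lists. Ranks are percentiles from 0 to 100 within a library, and ranks from lists of different lengths show no change.

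Genes, transcript starts and sequence came from the GRCm38.p6 assembly with the GENCODE M21 annotation. The annotation held 21826 protein-coding genes, and 6 noncoding genes were added because a list names them. No interval reached past a chromosome end. A promoter was 500 bp on either side of any protein-coding transcript start of the gene, and a gene's promoter peak had to touch it. Where peaks and not genes were counted, the centre of the peak decided. In the genomic distribution a promoter peak had its centre within 500 bp of a protein-coding start, and for sharing and density ratios within 500 bp of any annotated start, coding or not. A shared peak overlapped a peak of the other library by at least 1 bp. A distal peak had its centre more than 1 kb from every annotated start. The motifs were searched in the C57BL/6J reference, although 1 of the genome copies in these mice is CAST, so matches changed by a CAST variant were not seen.

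The 33 gene lists, the 35 motifs, the main tests, most of the alternatives and the rule for naming genes were chosen before the data were examined, and the alternatives added later are named as such. The lists covered skeletal muscle (myogenic regulators, satellite cells, fast or shared, slow or cardiac-shared and heart-restricted sarcomere genes, developmental myosin, excitation-contraction coupling, the neuromuscular junction, the dystrophin complex and costamere, muscle energy metabolism). They also covered cells that lie in or near muscle (fibroblasts, tendon, cartilage and bone, endothelium, pericytes and smooth muscle, Schwann cells, macrophages, lymphocytes, erythroid cells, adipocytes), and tissues foreign to it (keratinocytes, hepatocytes, neurons, pancreas, photoreceptors, germ cells). The last lists were housekeeping, hindlimb identity, forelimb or anterior identity, proliferation, immediate early and stress, circadian clock and imprinted genes. All 536 list entries matched a gene by symbol. The rule named a panel of 28 genes, in each list the 2 members with the strongest promoter peaks and the first 2 by alphabet without one, the genes nearest to the 10 strongest shared distal peaks, the 10 genes with the most shared distal peaks within 50 kb, and the genes nearest to the 5 longest low-FDR stretches, by mean length, found in both libraries. It took 158 genes, of which the text names the greater part, and some results are not reported here.

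Promoter peaks of a list were compared with those of all other protein-coding genes by a two-sided Fisher's exact test in each library, with Benjamini-Hochberg adjustment over the lists. A list was called only where both libraries passed 0.05 in the same direction. The median promoter rank of a list, with 0 for a gene without a peak, was set against 10000 random lists of the same size (two-sided permutation test). The mean number of shared distal peaks within 50 kb of the most upstream start was set against 10000 random lists matched on 5 classes of local gene density. The smallest p that these permutations can give is 0.0002. Motifs were searched as consensus strings on both strands in 150 bp about the centre of shared distal peaks, against windows 500 bp away outside peaks (two-sided Fisher's exact test, Benjamini-Hochberg adjustment over motifs). A consensus names a family of factors, not a factor. For each motif, the share of its matches in peaks that lay in a footprint was divided by the share of peak bases in footprints. Overlaps between libraries were set against 100 random circular shifts along the chromosomes.

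Alternatives took other promoter widths, distances, overlaps, thresholds, backgrounds and each library alone. A test of promoter peaks within 10 classes of promoter CpG ratio, the observed over the expected number of CpG pairs, was added after seeing the data. It first used a normal approximation and was then changed to an exact conditional test, with the same counts of called lists under both. The count of the longest stretches was corrected after its first output, so that a stretch of replicate 2 enters once.

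The tests were also run on simulated data, the one within CpG classes only after the data had been seen. Of lists planted with fewer promoter peaks, at 5% against 65% of genes, 99% were recovered. The recovery was 92% for lists planted with stronger promoter peaks and 86% for lists planted with 3 times as many distal peaks. At most 1.74% of unplanted lists were called. The test within CpG classes recovered 83.5%, and a motif planted in 20% of windows was found in every simulation. The planted distal effect was larger than any ratio found here, and lists with more promoter peaks were not planted. Simulated genes were drawn independently of their neighbours, so these rates do not carry over to the effects found. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.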

Results

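Accessible chromatin was mapped by DNase-seq in the gastrocnemius, a calf muscle made mostly of fast fibres in the adult, of 4-day-old male mice. There was 1 group of 2 biological replicates, so the data answer which genes, regions and sequence motifs were accessible in this muscle at this age. Replicate 1 gave 94295 peaks, replicate 2 gave 123291, and their mean was 108793 ± 20503 (SD, n = 2). The median peak was 180 bp wide in both libraries, and the peaks covered 0.647% of the genome in replicate 1 and 0.898% in replicate 2. Replicate 2, the library with more peaks, was 2.03 times as deep if 1 step of the density values is 1 cut scaled to depth. Footprints numbered 210189 in replicate 1 and 335055 in replicate 2.

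Most peaks of replicate 1 were found again in replicate 2. Of the peaks of replicate 1, 79.6% overlapped a peak of replicate 2, and of those of replicate 2, 60.8% overlapped 1 of replicate 1, where shifted peaks overlapped 1.76% and 1.36%. Among the strongest 10% of peaks, 99.9% of replicate 1 and 99.5% of replicate 2 were shared, and among the weakest 10%, 20.7% and 9.97%. Peaks centred within 500 bp of any annotated start were shared in 88.7% of cases in replicate 1 and 80.0% in replicate 2. Other peaks were shared in 75.99% and 54.6%. The densities of 73826 paired peaks had a Spearman correlation of 0.95 across peaks, which are not independent replicates. The scaled density was 1.41-fold higher in replicate 1 than in replicate 2 at the median paired peak.

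Promoters of protein-coding genes held the centres of 21.1% ± 3.0 of the peaks (SD, n = 2) but 1.30% of the genome. A further 7.47% ± 0.0639 of the peaks lay in exons, 31.8% ± 1.66 in introns and 39.7% ± 1.4 between genes. Among the strongest 10% of peaks the promoter share was 75.005% ± 4.44. A promoter peak was found for 65.3% of the 21826 protein-coding genes in replicate 1 and 67.03% in replicate 2, for 64.1% in both libraries and for 31.8% in neither. Promoters poor in CpG seldom had a peak: in the lowest of 10 classes of CpG ratio 2.84% of genes had one in replicate 1 and 4.63% in replicate 2, and in the highest 98.5% and 98.8%. Chromosome 11 had the most peaks per Mb of the autosomes, 58.6 in replicate 1 and 75.8 in replicate 2. The X chromosome, of which males carry 1 copy, had 17.6 and 22.9 peaks per Mb, which is 0.453 ± 0.000424 of the autosomal median (SD, n = 2). Per gene it had 3.04 peaks in replicate 1, against an autosomal median of 4.65, and 3.95 in replicate 2, against 6.08. At shared peaks the median density on X was 0.583 of that on the autosomes in replicate 1 and 0.593 in replicate 2.

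Muscle regulators with accessible promoters included Myod1 and Mef2c. Myod1, the bHLH factor that commits cells to the muscle lineage (chromosome 7, 46376474 to 46379099), had a promoter peak from 46376261 to 46376500 in replicate 1, with a density of 3.08 and 4 footprints, and from 46376261 to 46376520 in replicate 2, with a density of 1.54 and 5 footprints. Its mean rank was 85.3 ± 1.11 (SD, n = 2). Upstream of Myod1, shared distal peaks centred at -22973 and -34843 bp from the start had mean ranks of 74.2 and 72.8, and 1 downstream at 2717 bp had a mean rank of 86.0. This last peak held a CAGCTG E-box, the core sequence bound by myogenic bHLH factors, at 46379240 to 46379245, which lay in a footprint in both libraries (plus strand with 10 bp on either side, GGCAGACCTCCAGCTGTAGGGAATTC). Other E-boxes in shared peaks near Myod1, at -36438, -183 and 16819 bp, lay in no footprint. The E-box at -34833 bp lay in a footprint in replicate 2 only. Mef2c, a MADS-box partner of the myogenic bHLH factors, had a promoter rank of 83.7 ± 3.27 at a start downstream of its first, Pax7, the marker of satellite cells, 72.1 ± 11.8, and Myog, which acts in differentiation, 67.3 ± 3.02. A promoter rank takes the strongest promoter peak of each library, which need not be the same peak. For Pax7 it was 1 from 139832721 to 139833020 in replicate 1 and another from 139833101 to 139833320 in replicate 2. Myog had 10 shared distal peaks within 50 kb, and the strongest of them, centred at -45598 bp, had a mean rank of 93.9. The promoters of Myf5 and Myf6, which lie side by side on chromosome 10, had a peak in replicate 2 only, at ranks 54.4 and 30.7, and neither gene had a shared distal peak within 50 kb. The only shared peak there, centred at -781 bp from Myf5 with a mean rank of 50.8, lay outside the promoter and too close for a distal peak.

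Contractile genes were split between accessible and closed promoters. Des (desmin) had a promoter rank of 88.5 ± 0.669, Ckm (muscle creatine kinase) 83.8 ± 0.822, Ryr1 (the calcium release channel) 82.5 ± 1.23, Myh8 (perinatal myosin) 77.1 ± 0.231, Acta1 (skeletal actin) 71.9 ± 4.02, Tnnt1 (slow troponin T) 68.0 ± 4.48 and Ttn (titin) 56.0 ± 8.58 (SD, n = 2). The promoter peak of Dmd (dystrophin), at rank 70.6 ± 3.74, lay in an exon at an internal start (X chromosome, 85048201 to 85048400 in replicate 1). The only shared peaks within 50 kb of its most upstream start were intronic, at 7151 and 38969 bp, with mean ranks of 6.23 and 5.60. No promoter peak was found in either library for the adult fast myosins Myh1, Myh2 and Myh4, for the embryonic myosin Myh3, or for the slow and cardiac myosins Myh7 and Myh6. Tnnt3 (fast troponin T) had a promoter peak in replicate 1 only, at rank 54.8, but 14 shared distal peaks within 50 kb, 7 of them upstream within Lsp1, with mean ranks of up to 92.1. The Acta1 promoter peak, from 123894661 to 123895040 on chromosome 8 in replicate 1, held a CArG box (CCATATTTGG at -93 bp from the start), an MCAT element (AGGAATGT at -68) and an E-box at -243, and none of them lay in a footprint. At the synapse, Chrna1 (acetylcholine receptor alpha) had a promoter rank of 56.9 ± 1.6 and Musk (its clustering kinase) 61.3 ± 8.67. An E-box of the Musk promoter on chromosome 4, at 58285894 to 58285899 and -63 bp from the start, lay in a footprint in both libraries (GAGTTCTCCCCAGCTGGCCACGTCCA). Of the 28 panel genes, 18 had a promoter peak in both libraries and 7 in neither.

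Of the limb position genes in the panel, Tbx4, which marks the hindlimb, had a promoter rank of 71.2 ± 2.51 and 9 shared distal peaks, and Pitx1, its upstream regulator, 72.5 ± 1.25 and 7. Upstream of Tbx4 on chromosome 11, 5 shared distal peaks were centred from -44251 to -41611 bp from the start, and the strongest of them, from 85844721 to 85844900 in both libraries, had a mean rank of 94.2. Tbx5, the forelimb counterpart, had no promoter peak in either library and 1 shared distal peak. H19, an imprinted noncoding RNA, had a promoter rank of 87.1 ± 3.32 and 16 shared distal peaks within 50 kb.

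**Figure D1:**
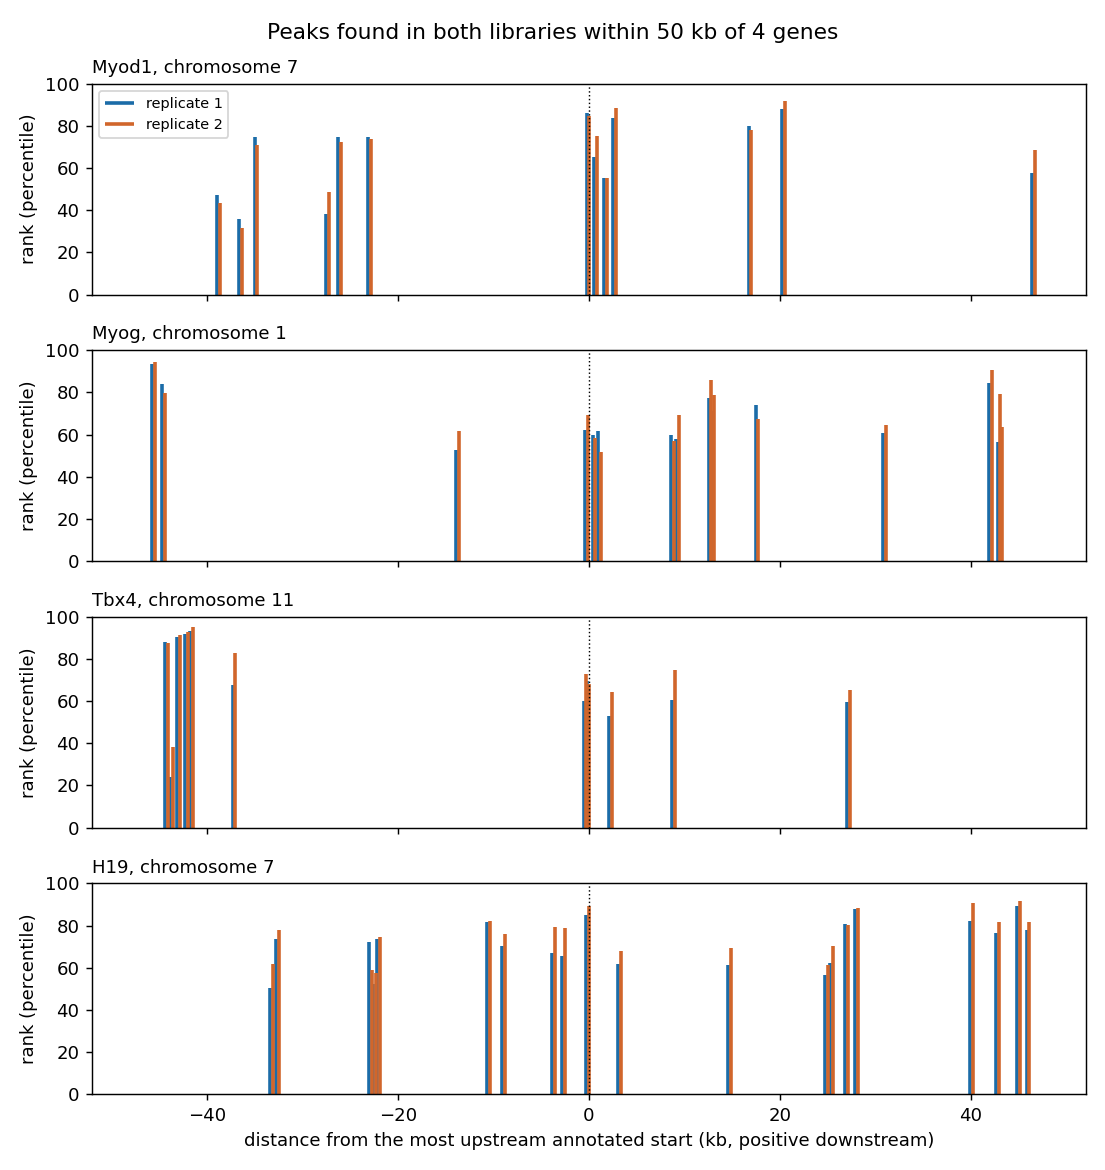
Peaks found in both libraries within 50 kb of Myod1, Myog, Tbx4 and H19, by distance in kb from the most upstream start (horizontal) and by density rank in percent within each library (vertical, replicate 1 blue and replicate 2 orange, lines drawn side by side). The group of peaks upstream of Tbx4 reaches a mean rank of 94.2, and the 16 distal peaks of H19 lie on both sides of the gene.

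All promoters of the housekeeping list were accessible, and those of several lists of other organs were mostly closed. A promoter peak was found in both libraries for all 25 housekeeping genes (Emc7 and Actb at mean ranks of 99.6 both) and all 18 proliferation genes (Ccna2, cyclin A, at 99.2 and Mcm5, a replication helicase subunit, at 98.9). So it was for all 18 immediate early and stress genes (Jund at 99.7, Gadd45b at 99.2) and all 17 circadian clock genes (Tef at 99.98, Nr1d2 at 99.4). Imprinted genes had one in 91.3% of cases in each library (Gnas at 94.1, Cdkn1c at 93.8, none at Ndn and Rtl1) and fibroblast genes in 92.9% ± 3.37 (Col6a2, a collagen VI chain, at 98.3, Tcf7l2 at 94.8, none at Ly6a), against 66.1% of other genes. These 6 lists passed in both libraries (Fisher's exact test, adjusted p from 0.000229 for housekeeping in replicate 1 to 0.0395 for fibroblasts in replicate 1). The fibroblast list did not pass with promoters of 200 bp, and neither it nor the imprinted list passed with the strongest 50% of peaks or the FDR 0.001 list. With the most upstream start only, the fibroblast, immediate early and imprinted lists did not pass.

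The 6 lists with fewer promoter peaks all belonged to blood cells or to other organs. Promoter peaks were found for 2 of 18 hepatocyte genes in each library (Foxa3 at rank 62.2 and Apob at 19.8, none at Alb and Ahsg) and for 2 of 16 lymphocyte genes in each (Pax5 at 91.7 and, in replicate 2 only, Lck, none at Cd2). They were found for 2 of 15 photoreceptor genes (Opn1sw at 95.6 and Rom1 at 93.2, none at Crx and Arr3). Macrophage genes had 2 of 17 in replicate 1 and 5 in replicate 2 (Fcgr3 at 91.9, Cd14 at 40.6, none at Adgre1 and Aif1), pancreas genes 3 and 5 of 15 (Nkx6-1 at 75.7, Ins2 at 73.6, none at Amy2b and Cel) and germ cell genes 4 of 18 in each (Dazl at 94.6, Sycp3 at 24.6, none at Acrv1 and Bmp15). Adjusted p ran from 4.63e-05 for hepatocytes to 0.0308 for pancreas, both in replicate 2 (Fisher's exact test). The peaks of Fcgr3, Pax5 and Ins2 lay in introns of these genes.

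The muscle lists did not pass against all genes in both libraries with the main settings. Dystrophin complex genes passed in both with promoters of 200 or 1000 bp, with the strongest 50% of peaks and with equal numbers of peaks. Keratinocyte genes passed with fewer promoter peaks with the strongest 50% of peaks and with the FDR 0.001 list. Without replicate 2, dystrophin complex genes (adjusted p = 0.0379) and muscle energy genes (0.0395) passed with more promoter peaks, and erythroid (0.0339) and keratinocyte genes (0.0129) with fewer (Fisher's exact test). Promoter peaks in replicates 1 and 2 were found for 11 and 14 of 15 myogenic regulators (Tead1 at 98.7, Mef2a at 98.1, none at Mymk, the fusion protein myomaker), for 14 of 15 satellite cell genes in each (Hey1 at 96.8, Spry1 at 96.5) and for 15 of 16 dystrophin complex and costamere genes in each (Dag1 at 99.9, Vcl at 99.5, none at Capn3). Fast or shared sarcomere genes had 18 and 17 of 25 (Tpm1 at 99.4, and Myom1 at 99.6 with a peak that lies in an intron of Myl12a), excitation-contraction coupling genes 14 and 13 of 19 (Asph at 96.9, Bin1 at 94.7, none at Casq1 and Clcn1) and muscle energy genes 18 and 17 of 20 (Slc25a4 at 99.3, Gys1 at 99.9 with a peak in Ruvbl2, none at Mb, myoglobin, and Ampd1). Slow or cardiac-shared sarcomere genes had 7 and 9 of 15 (Atp2a2 at 94.5, Tpm3 at 94.2, none at Myh7b). Heart-restricted ones had 8 and 6 of 14 (Myl4 at 98.4, Nppb at 61.0, none at Mybpc3). Some genes stand in more than 1 list, as Myl4 does. Developmental myosins had 3 of 6 in each (Myl4 at 98.4, none at Tnni1) and neuromuscular junction genes 11 and 10 of 13 (Chrnb1 at 94.8, Utrn at 92.3, none at Chrnd and Chrne). Among the other lists that did not pass in both, pericyte and smooth muscle genes had 13 of 14 in each (Des and Cspg4 both at 88.5, none at Higd1b). Through Des this list shares a gene with the contractile genes above. Tendon genes had 8 of 10 (Egr1 at 98.9, Egr2 at 93.9, none at Tnmd and Kera). Cartilage and bone genes had 10 of 15 (Sox9 at 87.1, Alpl at 80.2, none at Bglap and Col9a1), Schwann cell genes 10 of 15 (Prx at 98.2, none at Cdh19 and Gfap) and hindlimb genes 10 of 11 (Hoxc10 at 97.8, Hoxa10 at 95.2, none at Hotair). Endothelial genes had 11 and 12 of 17 (Egfl7 at 80.9, Kdr at 74.9, none at Pecam1 and Erg), adipocyte genes 9 of 14 in each (Cebpa at 97.8, Ebf2 at 96.8, none at Adipoq and Cidec). Erythroid genes had 5 and 7 of 15 (Epor at 86.0, Ank1 at 73.9, none at Alas2 and Ermap) and keratinocyte genes 4 and 7 of 15 (Krt10 at 93.7, Perp at 41.6, none at Dsg3 and Ivl). Neuron genes had 11 and 12 of 18 (Dlg4 at 90.9, Slc17a6 at 83.8, none at Elavl3 and Neurod1) and forelimb or anterior genes 8 and 9 of 13 (Emx2 at 84.2, none at Hoxb1 and Hoxc4).

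Within classes of promoter CpG ratio, a comparison added after seeing the data, the called lists were largely others. Muscle energy genes had 18 promoter peaks where 9.81 were expected in replicate 1 and 17 against 10.4 in replicate 2 (adjusted p = 0.000109 and 0.00443, exact conditional test). Excitation-contraction coupling genes had 14 against 7.86 and 13 against 8.38 (adjusted p = 0.00205 and 0.0376, exact conditional test). Fibroblast genes had 19 against 11.6 and 20 against 12.2 (0.000165 and 7.48e-05, same test). Pericyte and smooth muscle genes, Des among them, had 13 against 7.51 and 13 against 7.99 (0.00534 and 0.0124, same test). Neuron genes had fewer, 11 against 15.5 and 12 against 15.8 (0.009 and 0.0376), as had germ cell genes, 4 against 9.24 and 4 against 9.79 (0.00684 and 0.00443). Hepatocyte genes did not pass, with 2 against 4.93 in replicate 1 and 5.58 in replicate 2, nor did photoreceptor genes, with 2 against 4.46 and 5.01. Lymphocyte genes, with 2 against 4.11 and 4.63, did not pass. Neither did pancreas genes, with 3 against 6.39 and 5 against 6.78, or macrophage genes, with 2 against 3.76 and 5 against 4.28. Housekeeping genes (25 against 23.7 in replicate 1), proliferation genes (18 against 17.2) and immediate early genes (18 against 17.4) could not pass, since nearly all genes of their CpG classes had a promoter peak. Circadian clock genes (17 against 15.1 in replicate 1 and 15.2 in replicate 2) could not pass in both libraries either. With all 17 at a peak, the highest count possible, the p in replicate 2 was 0.0646 before adjustment (exact conditional test). Imprinted genes (21 against 19.6 in replicate 1) did not pass.

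**Figure D2:**
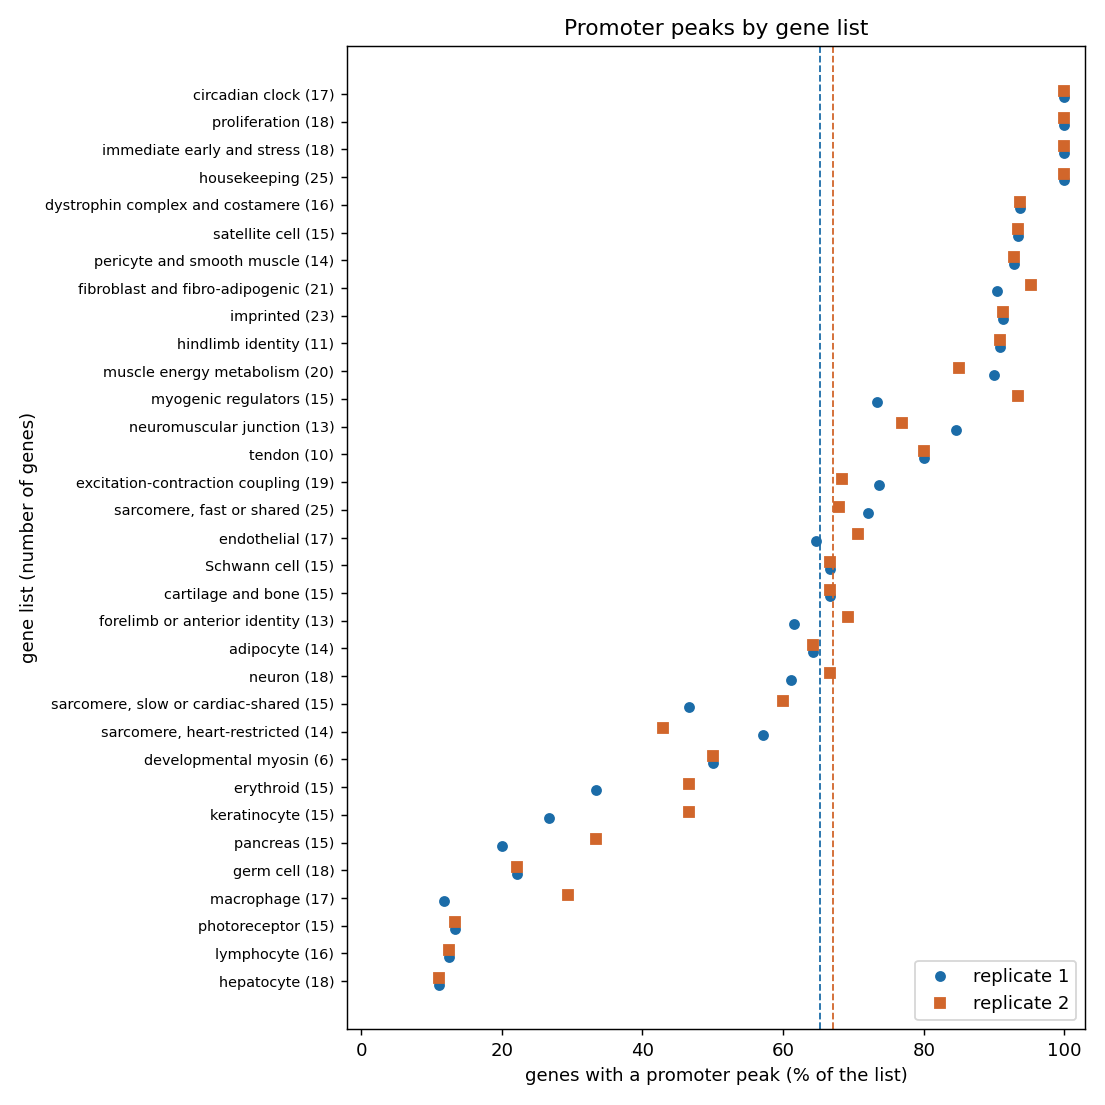
Share of each list's genes with a promoter peak, in percent, in replicate 1 (blue circles) and replicate 2 (orange squares), with the number of genes in brackets and the share among other genes as dashed lines. Circadian, proliferation, immediate early and housekeeping genes stand at 100% in both libraries and hepatocyte genes at 11.1%.

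By the median of a list, the strongest promoter peaks belonged to 4 of these broadly active lists. Single genes of other lists, such as Dag1 and, with a peak in Ruvbl2, Gys1, ranked as high. As a fraction of the highest rank, the median promoter rank in replicate 1 was 0.971 for housekeeping genes, where random lists of that size had 0.748, 0.968 for circadian clock, 0.963 for immediate early and 0.958 for proliferation genes. In replicate 2 it was 0.978 for housekeeping genes, where random lists had 0.798, 0.979 for circadian clock, 0.975 for immediate early and 0.969 for proliferation genes. These 4 lists were stronger in both libraries (permutation test, adjusted p from 0.0033 to 0.0148). The other direction could not be tested this way for lists made mostly of closed genes. Their median was 0, the lowest value possible, and random lists reached it often enough that the unadjusted permutation p at a median of 0 was 0.0746 to 0.201. Where only genes with a promoter peak were compared, proliferation genes were no longer called stronger and 8 lists were weaker in both libraries: fast or shared and heart-restricted sarcomere, neuromuscular junction, cartilage and bone, endothelial, keratinocyte, neuron and germ cell genes. Random lists in these comparisons of rank were not matched on promoter CpG ratio, and whether it accounts for the differences was not tested.

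Distal peaks were more frequent than in random lists around some of the muscle and connective tissue lists and around immediate early, circadian, hindlimb and imprinted genes. The 15 myogenic regulators had 5.27 shared distal peaks per gene within 50 kb against 2.36 in matched random lists, a ratio of 2.23 (permutation test, adjusted p = 0.00792). Fast or shared sarcomere genes had a ratio of 1.76 (adjusted p = 0.0147) and excitation-contraction coupling genes 1.84 (0.0147, permutation test), with 14 peaks around Tnnt3 and 11 around Bin1. Fibroblast genes stood at 2.13 (adjusted p = 0.0066, permutation test) and Schwann cell genes at 2.14 (0.0088, same test). Pericyte and smooth muscle genes, a list that also holds Des, stood at 1.99 (0.0211, same test) with 17 peaks around Cspg4. Hindlimb genes stood at 2.44 (0.00792), circadian clock genes at 2.05 (0.00943), and imprinted genes at 2.45 with 16 peaks around H19 and 12 around Cdkn1c. Immediate early and stress genes had the highest ratio, 2.77, with 7.17 peaks per gene, among them 13 around Gadd45b and 10 around Jund. For these and the imprinted genes the adjusted p was 0.0033, from the smallest p the permutations can give.

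Of the 33 lists, 10 passed with more shared distal peaks and 0 with fewer (permutation test); at an unadjusted p under 0.05 the counts were 16 and 0. Among the 23 that did not pass, ratios ran from 0.684 for keratinocyte genes to 1.97 for tendon genes. Tendon and satellite cell genes (ratio 1.80) had an adjusted p of 0.0511, developmental myosins, with 6 genes and a ratio of 1.84, a permutation p of 0.182 after adjustment, slow or cardiac-shared sarcomere genes (1.72) 0.0581 and forelimb or anterior genes (1.46) 0.258. Housekeeping (1.55) and proliferation genes (1.63) came as close, also at 0.0581, and dystrophin complex genes (1.73) had 0.0619 (permutation test). Each library alone called 6 lists. Without replicate 1 the myogenic, fibroblast, hindlimb, immediate early, circadian and imprinted lists passed, and without replicate 2 the fast sarcomere, fibroblast, Schwann cell, hindlimb, immediate early and imprinted lists. Excitation-contraction coupling genes and pericyte and smooth muscle genes passed in neither library alone. With the FDR 0.001 list these 2 lists and the Schwann cell and hindlimb lists did not pass. Hox genes of a cluster share their neighbourhoods, and with 1 gene per 100 kb the hindlimb list kept 6 genes and a ratio of 2.29 with an adjusted p of 0.0538 (permutation test). Within 100 kb the hindlimb and the pericyte and smooth muscle lists did not pass.

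**Figure D3:**
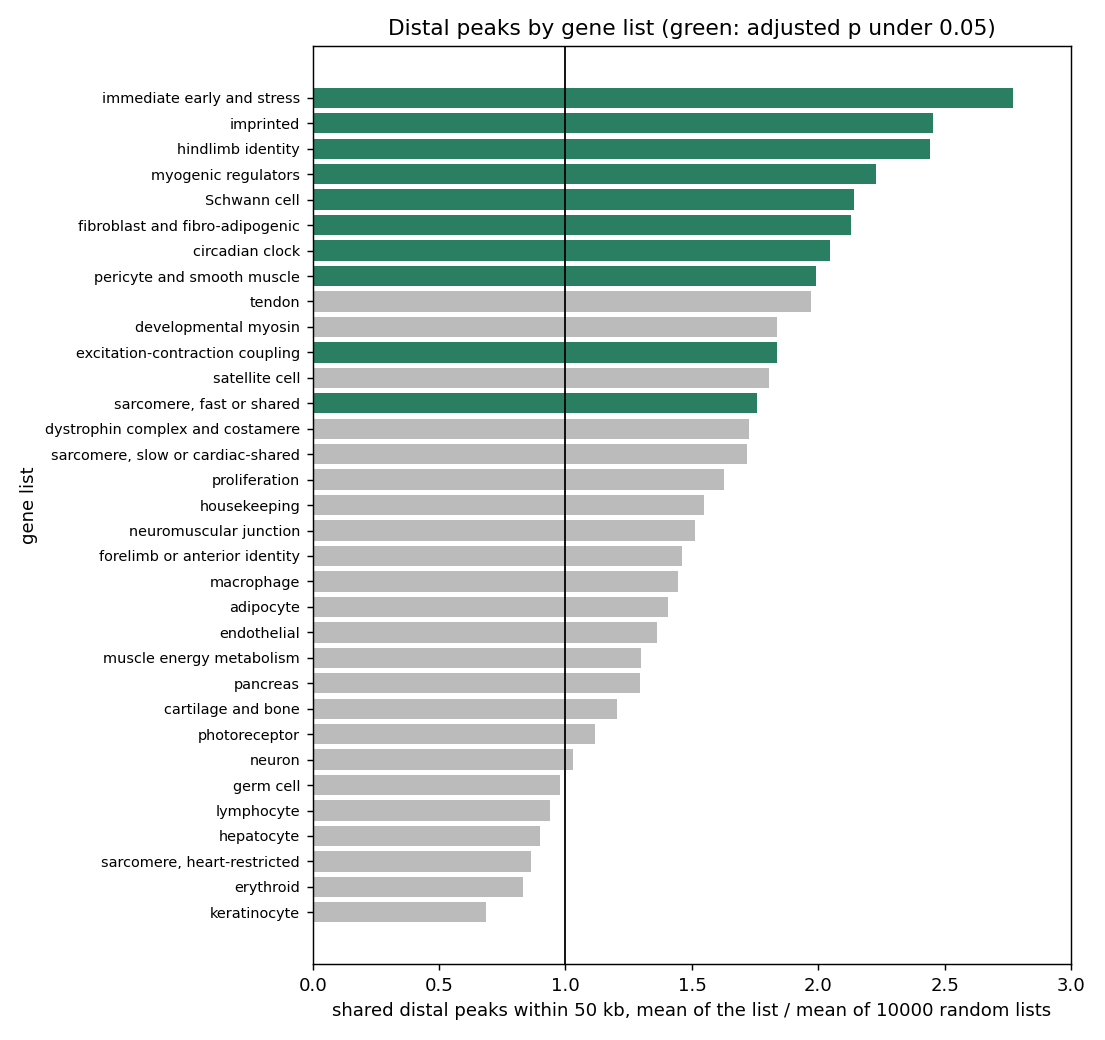
Mean number of shared distal peaks within 50 kb of the genes of each list, divided by the mean of 10000 random lists matched on gene density, where 1 means no difference. Green bars mark the 10 lists with an adjusted p under 0.05, from 1.76 for fast or shared sarcomere genes to 2.77 for immediate early and stress genes.

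The neighbourhood with the most distal peaks lay on chromosome 11. There Kdm6b, a histone demethylase, had 28 shared distal peaks within 50 kb and no promoter peak in either library, and its neighbours Cyb5d1, Naa38 and Tmem88 had 27 each and Chd3, a chromatin remodeller, 24, in windows that overlap. Ptgis, prostacyclin synthase, had 27, Actg1, cytoplasmic gamma-actin, 26, Gm21887 24 and Dohh 23, where the mean over genes was 2.53. In the pair of strong distal peaks nearest to Gm21887, described below, 100% of the 24-base words occur more than once in the reference. By mean length over the libraries, the longest stretches of low FDR found in both lay at Adcy4, an adenylate cyclase (2086 bp in replicate 1 and 10321 bp in replicate 2), Hic1, a transcriptional repressor (855 and 11296 bp), Smarcd3, a subunit of the BAF remodelling complex (4584 and 6266 bp), Pcdh7, a protocadherin (3873 and 6367 bp), and Actg1 (4706 and 5265 bp).

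The 10 strongest shared distal peaks are described by position and nearest gene, and nearness to muscle genes was not tested. The first, from 99735821 to 99736040 on chromosome 15, lay in the 3' UTR of Cers5, 10313 bp from the start of Cox14, with densities of 41.3 and 38.3 in replicates 1 and 2. The next lay in the 3' UTR of Lars2 near Limd1 (chromosome 9, 123461921 to 123462080, densities 27.8 and 22.6) and in the 3' UTR of Ubqln1 (chromosome 13, 58177641 to 58177800, 23.4 and 20.9). A pair lay in an intron of Mid1 on the X chromosome, nearest to Gm21887, with densities of 40.6 and 12.3 at the first and 15.04 and 11.5 at the second. Others were nearest to Igf2bp3 (22.4 and 14.1), Atp23 (19.4 and 14.3, 389637 bp away), Zfp395 (20.2 and 11.1) and Jarid2 (17.4 and 10.1, in an intron). In 5 of the 10 strongest more than 50% of the 24-base words occur more than once in the reference, namely those near Limd1, Igf2bp3 and Jarid2 and the pair in Mid1.

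The myogenic E-box was the motif found in most distal peaks. CAGCTG occurred in 25.6% of shared distal peaks and 6.80% of flanking windows, 3.76-fold more often (Fisher's exact test, adjusted p of 0 in double precision), and by library the fold was 3.43 ± 0.267 (SD, n = 2). The core of CTCF, the insulator protein, occurred in 8.83% against 0.0423%, 206-fold. The MCAT element of TEAD factors occurred in 4.10%, 1.62-fold above the flanks (1.61e-51), and the AP-1 site in 4.52%, 1.77-fold (3.39e-76). Further motifs above the flanks included the NFI palindrome (17.7-fold), YY1 (8.78-fold in 7 peaks, but 4.25-fold without replicate 2 and 25.8-fold without replicate 1), NRF1 (7.84-fold), CEBP (4.20-fold, 2.68-fold without replicate 1), CRE (3.63-fold), SP/KLF (3.11-fold), ETS (2.58-fold), EBF (2.44-fold), the E-boxes CACGTG (1.59-fold) and CACCTG (1.17-fold), KLF short (1.56-fold), the glucocorticoid receptor (1.48-fold), PU.1 (1.38-fold), ETS core (1.22-fold) and NFY (1.06-fold, adjusted p = 0.034 by Fisher's exact test). The REST core, bound by the repressor of neuronal genes, was found in 86 distal peaks and 0 flanking windows (4.26e-38).

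Below the flanks were homeodomain (0.311-fold), ERR (0.391), PITX or OTX (0.408), GATA (0.43), T-box (0.551), FOXA (0.718), the CArG box of SRF (0.808), RUNX (0.849) and the nuclear receptor DR1-like motif (0.232, in 3 peaks). Without replicate 1 the last stood at 0.666 and did not pass, and without replicate 2 it stood at 0.444. MEF2, the partner of the myogenic factors, was found in 0.304% of distal peaks against 0.254% (1.20-fold, adjusted p = 0.113 by Fisher's exact test), and SOX (0.939-fold, 0.0931) and HNF4-like (1.11-fold, 0.494) did not pass either. Without replicate 1 MEF2 passed (1.26-fold). Without replicate 2 SOX passed on the lower side (0.927-fold). HNF1 was found in 0 distal peaks and 1 flanking window, and HOX or PBX in none (Fisher's exact test, p of 1 for both before and after adjustment). Of the 35 motifs 21 were above the flanks and 9 below. Distal peaks had a mean GC content of 54.7% and flanking windows 45.3%. Against 3822 windows matched on GC content 10 motifs were above and 6 below: the myogenic E-box stood at 2.61-fold (adjusted p = 9.55e-125, Fisher's exact test), MCAT at 1.86-fold and AP-1 at 1.83-fold, while CACCTG (0.823-fold) and KLF short (0.728-fold) passed on the lower side and FOXA on the upper (1.62-fold).

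Matches of some motifs lay in a footprint more often than peak bases did, and those of others less often. All peaks were used here, promoter peaks included, without matching on peak strength or base composition. Footprints covered 16.6% of GC and 12.5% of AT bases of peaks in replicate 1, and 18.3% and 13.5% in replicate 2. Whether promoter peaks, peak strength or base composition account for the ratios was not tested. Matches of the REST core lay in a footprint 5.99 ± 0.118 times as often as peak bases did (SD, n = 2), those of CTCF 5.93 ± 0.158, NFI 5.14 ± 0.278, NRF1 4.96 ± 0.135, CRE 4.37 ± 0.3, SP/KLF 3.98 ± 0.0326, ETS 2.97 ± 0.0485, YY1 2.70 ± 0.0158 and EBF 2.65 ± 0.31. For CTCF this was 92.3% ± 2.91 of its matches in peaks. The myogenic E-box stood at 1.37 ± 0.00111, with 21.4% ± 1.23 of its matches in a footprint. CEBP, KLF short, CACGTG, CACCTG, NFY and ETS core lay between 1.19 and 2.01, so that 16 motifs were above 1 in both libraries. AP-1 stood at 0.526 ± 0.0229, MEF2 at 0.578 ± 0.0804, MCAT at 0.712 ± 0.0413, GATA at 0.376 ± 0.0211, the glucocorticoid receptor at 0.315 ± 0.102 and FOXA at 0.224 ± 0.0157. Of the footprints of replicate 1, 61.0% overlapped 1 of replicate 2 by at least 50% of the shorter, and of those of replicate 2 37.5% overlapped 1 of replicate 1, where random shifts gave 0.232% and 0.147%. Footprints of replicate 1 moved by 50 bp still overlapped in 28.3% of cases in either direction, and moved by 100 bp in 12.6% or 12.7%.

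**Figure D4:**
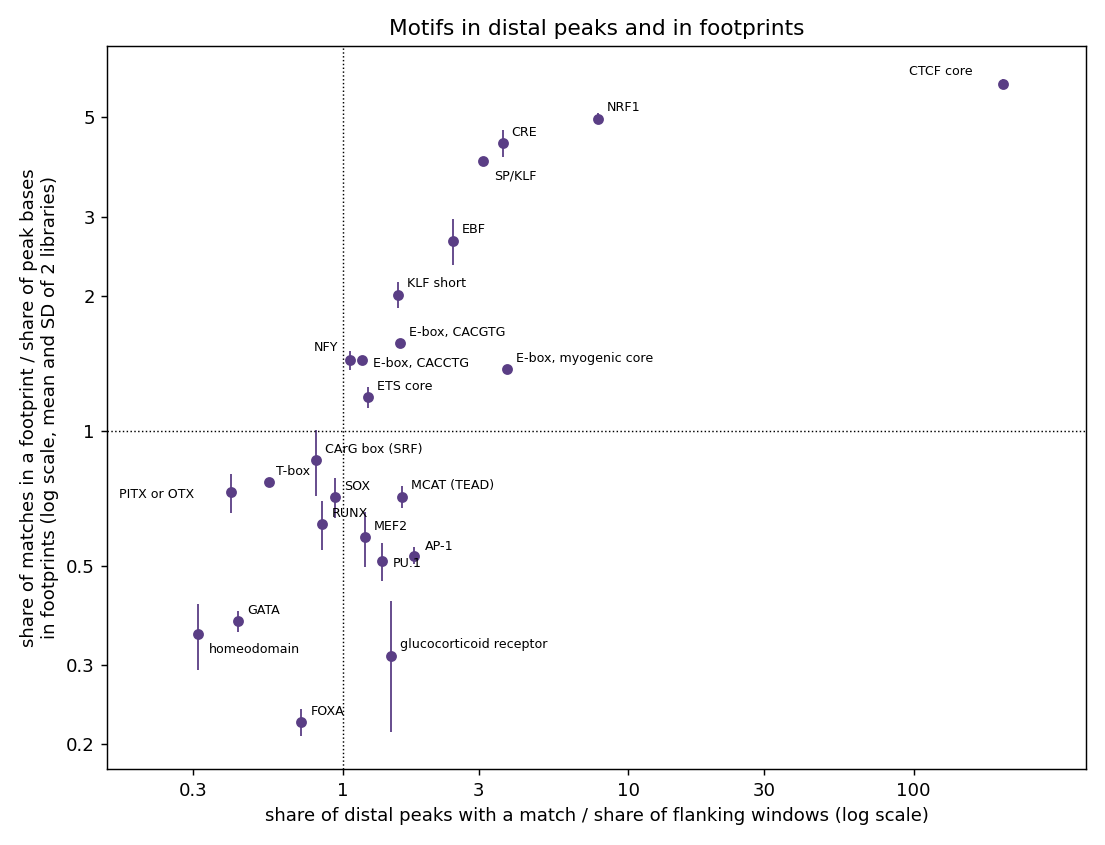
Motifs with at least 100 matched distal peaks, 1 of them not drawn, by the share of distal peaks with a match over that of flanking windows (horizontal, log scale) and by the share of matches in a footprint over the share of peak bases in footprints (vertical, log scale, mean and SD of 2 libraries). The vertical values take matches in all peaks, promoter peaks included. CTCF stands highest on both axes, and the myogenic E-box at 3.76-fold and 1.37.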

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

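The tests within CpG classes, on the most upstream start, on equal numbers of peaks for promoter peaks, with low-FDR stretches for peak numbers and promoter peaks, with the FDR 0.001 list for peak numbers and distal peaks and with 1 gene per 100 kb were chosen after seeing the data, as was leaving out a library for the promoter share, the X chromosome and the footprint motifs.

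The count of peaks per library moved from 108793 to 54363.5 when only the strongest 50% were kept, which follows from the choice, to 64077.5 in the FDR 0.001 list, and stood at 191684 as stretches. The shared share moved from 70.2% to 84.5% for the strongest 50%, the promoter share in the genomic distribution of peaks to 26.9% with 1000 bp, and the X ratio to 0.423 with stretches. Lists with more promoter peaks numbered 3 on the most upstream start against 6, and lists with fewer numbered 2 within CpG classes against 6. Lists with weaker promoter peaks numbered 8 with only genes with a peak as background against 0, where the test on all genes could not call lists with a median of 0. Lists with more distal peaks numbered 6 with the FDR 0.001 list, and from 6 to 6 with each library left out, against 10. Motifs above the background numbered 10 when matched on GC content, against 21. Matching also cut the background from 80301 to 3822 windows. ETS (from 2.58 to 5.77-fold) and CEBP (from 4.20 to 4.60-fold) lost their call with higher folds, while SP/KLF (from 3.11 to 1.11-fold) lost it with a lower one. The cause was not tested.

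Folds turned with promoter peaks as background, which is another comparison by construction: CACGTG 0.586, CRE 0.179, ETS 0.0768, ETS core 0.531, SP/KLF 0.123, NFY 0.41, NRF1 0.066, YY1 0.0307, KLF short 0.661 and CEBP 0.341 fell below 1, and CArG 1.19, RUNX 3.17, ERR 1.92, GATA 2.32, FOXA 2.06, SOX 1.62, PITX or OTX 1.95, homeodomain 2.82 and T-box 2.57 rose above it. Matched on GC content, CACCTG 0.823, KLF short 0.728 and PU.1 0.879 fell below 1 and CArG 1.24, RUNX 1.08 and FOXA 1.62 rose above it. The cause was not tested.

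The 4 lists with stronger promoter peaks stayed called with 1000 bp and without either library. The 6 lists with fewer promoter peaks stayed called under every setting except within CpG classes, where of them only germ cell genes did. With only genes with a peak as background, proliferation genes were no longer stronger. Stricter footprints and equal numbers of the strongest footprints were not run, since every footprint carries the same value, the HOX or PBX motif had no match to test for footprints, and the shared share and the footprint overlap cannot be had with a library left out. No paired analysis was possible because there is 1 group.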

Other observations

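The tests of depth alone and of the mix of cell types were chosen only after their results were seen.

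Distal peaks near the genes of the neuromuscular junction carried the CAGCTG E-box in 37.0% of 46 cases, those near developmental myosins in 32.0% of 25, and those near fast or shared sarcomere genes in 27.5% of 102. The share was 26.7% of 90 for excitation-contraction coupling, 25.0% of 64 for satellite cell and 25.0% of 28 for heart-restricted sarcomere genes. It was 24.2% of 62 for slow or cardiac-shared sarcomere genes, 21.5% of 79 for myogenic regulators, 20.9% of 67 for dystrophin complex and 20.3% of 69 for muscle energy genes. Near neuron genes the share was 8.51% of 47 and near hepatocyte genes 9.76% of 41, while near pancreas genes it was 39.1% of 46 and near keratinocyte genes 45.8% of 24. These shares per list were not tested.

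It was asked whether distal peaks near muscle genes carry the E-box more often than others. Within 50 kb of the 59 genes of the myogenic regulator, fast sarcomere and excitation-contraction lists, 25.5% of 271 distal peaks had it, against 25.6% of the others (permutation p = 0.712, two-sided, over 10000 gene sets matched on the number of distal peaks). The hypothesis found no evidence in this test: the E-box was as frequent in distal peaks far from these genes.

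The strongest distal peaks may in part come from sequence with several copies in the reference. The median share of 24-base words found more than once was 43.9% over the 10 strongest, above the highest of 1000 random sets of 10 distal peaks (0.645%). Repeats marked in the reference do not account for it, with 5.26% of bases against 8.86% in random peaks. In the peaks near Cox14, Ubqln1 and Zfp395 0% of the words had a second copy, so copies leave these open. No biological explanation was tested.

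The scaled density of shared peaks was higher in replicate 1, by 0.50 on the log2 scale at the median. If the densities are scaled to depth, which is assumed, depth alone would have left a median near 0. A trend with GC content is a candidate explanation for part of it: the log2 ratio rose with the GC content of a peak, with a Spearman correlation of 0.251 in other peaks and 0.298 in promoter peaks, but in the lowest of 5 GC classes replicate 1 was still 1.27-fold higher. A different mix of cells in the libraries stays open, since the lowest adjusted p over 25 lists at their promoter peaks was 0.0583 (permutation test), with 0 lists under 0.05 after adjustment and 8 before. The lowest were fibroblast and erythroid genes, lower in replicate 1, and circadian genes, higher. Random genes in this test were not matched on GC content, with which the ratio rose. The test therefore cannot tell a different mix of cells from the trend with GC content.

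Distal peaks around the called lists were set against strong promoters and CpG-rich promoters as explanations. With random lists matched on promoter rank, all 10 lists passed again, with ratios from 1.65 to 2.23, and with lists matched on promoter CpG ratio all 10 passed, from 1.79 to 2.33. Slow or cardiac-shared sarcomere genes passed as well under both (1.83 and 1.87), and macrophage genes under the first (1.95, adjusted permutation p = 0.0403). A gathering of distal peaks around strong or CpG-rich promoters in general is therefore unlikely to be the whole source. That these lists hold genes regulated in this muscle is a hypothesis from the same data, which no contrast was there to test, and each library alone called 6.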
